A study of Fagopyrum tataricum with 12 samples.

How the data were processed

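RNA sequencing of leaf and stem from Tartary buckwheat seedlings of cultivar Dingku1 gave 12 libraries in 4 groups of 3: control at 0 h and 20% PEG-6000 for 2, 4 and 8 h. The raw read counts per gene were deposited by the authors as whole numbers for 26750 genes. FPKM were also deposited by the authors, and each value was checked to equal the count over the library's total and a gene length, times a constant (largest relative difference 1.69e-07). All these lengths were multiples of 3 (median 1062), so they are called coding lengths here. The tools fastp, HISAT2, HTSeq and DESeq2 are named, without versions or roles, per the submitters' processing notes. The genome build and annotation release were not given, and no reference genome was used. Gene symbols (16389 genes) and descriptions (20157 genes) were those deposited with the values, 26546 genes carry a chromosome in their identifier and 204 a scaffold.

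Library totals ranged from 30468104 to 37395814 counted reads, and 23909 to 24208 genes had a count in a library. Counts were scaled by TMM (factors 0.936 to 1.10) and tested by the edgeR quasi-likelihood method (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in 1 fit of all 12 libraries, after filterByExpr by group with a minimum count of 10 and a minimum total of 15, which removed 4687 genes and left 22063. Contrasts were each PEG time against 0 h, 4 h against 2 h, 8 h against 4 h, and any difference between the 4 times. The difference between 8 and 2 h was tested too. P-values were adjusted by the Benjamini-Hochberg method within each contrast at a false discovery rate of 0.05, with no fold minimum. Adjusted p-values given for single genes are those of edgeR. A level in a group without any count would have been given as a bound, set at 3 counts, and no named gene needed one.

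Named genes followed a rule written before the data were examined. For each PEG time it took the 6 largest rises and the 6 largest falls among genes that passed the threshold, had a mean of at least 10 CPM over the 12 libraries, had all 3 treated libraries beyond all 3 controls and had a described product. For each gene list it took up to 3 members with the smallest p over any time, and up to 6 for the phenylpropanoid, flavonol, anthocyanin, glycosylation and MYB lists. This gave 153 genes. Enzyme steps and protein classes within lists were grouped after the values were seen.

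The 38 gene lists were text searches of symbols and descriptions, also fixed before the data were examined. Accidental text matches were then removed from the descriptions alone, before any expression value was tested, and organelle genes were taken out of the photosystem and Calvin cycle lists. The flavonoid MYB subgroups are part of the MYB list, and the cell wall expansion list includes cellulose synthase genes. Lists were tested by camera with a preset correlation of 0.01 between genes, adjusted over 38 lists and 3 times. The contrasts of neighbouring times were adjusted as a separate family. Camera with the correlation estimated from the data and fry were the alternatives.

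Alternatives to the fit were DESeq2 size factors in edgeR, DESeq2 (1.42.0), no low-count filter, a stricter filter (1 CPM in 3 libraries and a mean of 5 CPM), limma on log2 of the deposited FPKM with 1 or 0.1 added (FPKM of 1 in 3 libraries, or no filter), replicate number as a block, only the 6 libraries compared, a 2-fold minimum, and leaving out each library. Library-size scaling without TMM was added after the data were seen. Labels were also split at random (100 splits of all libraries, and all 10 splits of each 6). Pathway names deposited with the genes were tested by camera as an exploration. List medians were compared with 1e+05 permutations, and a spline of 5 degrees of freedom on coding length and abundance was fitted with 2000 bootstraps.

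The code was tested on simulated data drawn from the real means and library sizes, with 200 genes changed and 30 more raised as a list. For 2 h against 0 h edgeR recovered 79.1% of genes changed by 0.5 on the log2 scale, 86.6% by 1 and 95.5% by 2, with 8 false calls among 200 calls. Few genes changed in the simulation, while 63.2% of tested genes were called at 2 h in the real data. These rates may therefore not carry over. A list of 30 raised genes was found and a list of 30 unchanged genes was not. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.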

Results

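The series measured gene expression in Tartary buckwheat (Fagopyrum tataricum), cultivar Dingku1, a grain crop rich in the flavonol glycoside rutin. RNA was sequenced from the leaf and stem of hydroponic seedlings at the 2-leaf stage that had stood in 20% PEG-6000, a polymer that lowers the water potential of the medium, for 2, 4 or 8 h, and from control seedlings in Hoagland's nutrient solution at 0 h. Each of the 4 groups held 3 libraries, 12 in all. The title concerns MYB factors and flavonoid synthesis under drought, so the comparisons ask which genes differed from the control after each time in PEG and how the flavonoid pathway and its MYB regulators moved with them. Counted reads per library ranged from 30468104 to 37395814 over 26750 genes, of which 22063 were tested. Levels below are CPM after TMM scaling, as mean ± SD over the 3 libraries of a group (n = 3), and folds are those of the edgeR fit. Gene identifiers carry the chromosome (Ft1 to Ft8), while positions and the genome build were not given in the sources used here.

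The 4 groups were far apart relative to their replicates. Spearman correlations of log2 CPM lay between 0.9966 and 0.9970 within groups and between 0.895 and 0.977 across groups, and the common biological coefficient of variation was 4.90%. The first principal component (53.03% of the variance) ordered the groups by time, and the second (29.5%) set the 8 h libraries apart from those of 2 and 4 h. The mean correlation with the control fell from 0.940 at 2 h to 0.904 at 4 h and 0.897 at 8 h. The labels do not say whether the libraries of a group came from separate plants, pools or repeated extractions, and a spread as low as 4.90% leaves repeated extractions possible, so the p-values measure the spread between these samples and may not cover that between plants. The series holds no untreated library at 2, 4 or 8 h, so hours in PEG and time of day go together throughout. Differential expression passed the threshold for most genes: 13954 of 22063 at 2 h (6970 higher, 6984 lower), 16060 at 4 h (7745 higher, 8315 lower) and 15641 at 8 h (8036 higher, 7605 lower), by edgeR at a false discovery rate of 0.05. With a change of at least 2-fold as well, 4101, 5976 and 5957 genes remained in these counts.

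**Figure D1:**
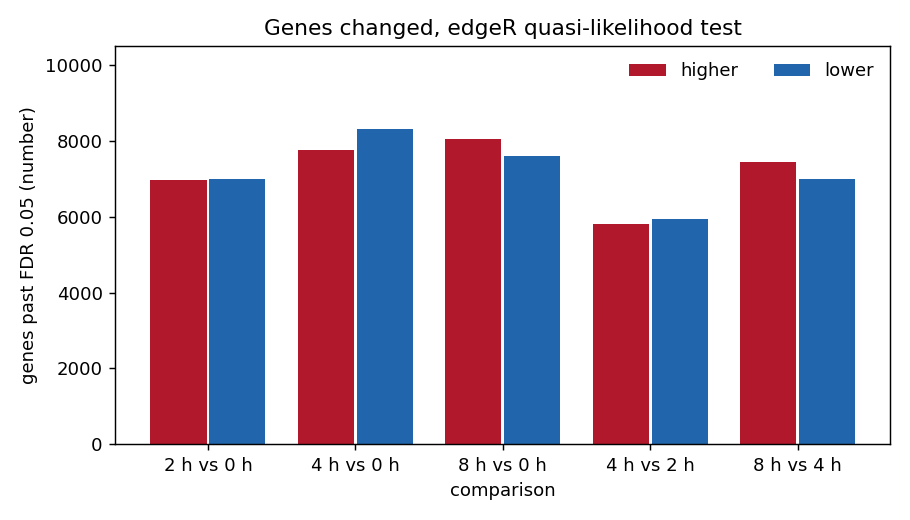
Number of genes past a false discovery rate of 0.05 (vertical axis) in each comparison (horizontal axis), as bars for genes higher and lower in the first-named group. At 2 h the bars stand at 6970 and 6984 genes, and in the comparison of 4 h with 2 h they stand at 5803 and 5926.

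After 2 h in PEG, genes of abscisic acid (ABA) synthesis and signalling, late embryogenesis abundant proteins and several families of stress transcription factors were higher than in the control, while most genes of the photosynthetic apparatus were lower. The calls of the photosynthesis lists, unlike those of the ABA and late embryogenesis lists, were lost with an estimated correlation (adjusted p = 0.203 for light harvesting). NCED1 (evm.TU.Ft6.1013), for the dioxygenase of the committed step of ABA synthesis, rose from 1.98 ± 0.306 to 209 ± 10.3 CPM (n = 3 each), 105-fold. PP2C51 (evm.TU.Ft1.1645), a protein phosphatase of the class inhibited by ABA receptors, rose from 3.72 ± 0.375 to 403 ± 2.57 CPM, 108-fold. CAB36 (evm.TU.Ft8.3607), a chlorophyll a-b binding protein, fell from 8719.9 ± 344 to 4267 ± 183 CPM.

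The 6 largest rises among well-expressed genes were led by DREB1B (evm.TU.Ft5.446), a factor that binds dehydration-responsive elements, which went from 0.346 ± 0.0966 to 130.01 ± 3.35 CPM, a log2 change of 8.54 (SE 0.0927). EDL3 (evm.TU.Ft7.3497), an F-box protein, reached 284 ± 2.44 CPM (323-fold), the sugar transporter SWEET14 (evm.TU.Ft5.554) 26.7 ± 0.302 CPM (218-fold) and the late embryogenesis abundant gene ECP63 (evm.TU.Ft3.119) 78.6 ± 1.47 CPM (182-fold). The geraniol 8-hydroxylase CYP76B6 (evm.TU.Ft2.630) rose 163-fold and the peroxidase gene evm.TU.Ft3.3736 122.5-fold. Among the 6 largest falls, the terpene synthase TPS8 (evm.TU.Ft3.1285) went from 81.1 ± 6.13 to 0.0929 ± 0.0882 CPM (log2 change -9.70, SE 0.177) and the laccase LAC14 (evm.TU.Ft1.512) from 89.1 ± 8.58 to 0.295 ± 0.129 CPM. The lipoxygenase LOX2.1 (evm.TU.Ft2.1281) fell from 104 ± 6.46 to 3.64 ± 0.325 CPM, and the major latex-like genes MLP34 (evm.TU.Ft6.1095) and MLP31 (evm.TU.Ft6.1121) from 214 ± 14.1 to 5.81 ± 0.833 and from 46.2 ± 8.49 to 2.01 ± 0.542 CPM. CHLN (evm.TU.Ft8.4768), annotated as a nicotianamine synthase, fell to 1.39 ± 0.294 CPM from 35.6 ± 3.06. The largest adjusted p among these 12 genes was 1.32e-26 (edgeR).

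In the list of phenylpropanoid entry enzymes, which lead from phenylalanine to the precursors of flavonoids and lignin, 9 of 11 tested genes were higher and 2 lower at 2 h. The list rose against all other genes (camera adjusted p = 0.00686, and 0.0466 with an estimated correlation). PAL3 (evm.TU.Ft5.1292), a phenylalanine ammonia-lyase, rose 2.63-fold from 54.1 ± 2.57 to 142 ± 0.774 CPM, 4CL1 (evm.TU.Ft3.946) 2.60-fold to 105 ± 3.55 CPM and the cinnamate 4-hydroxylase CYP73A4 (evm.TU.Ft2.5323) 1.98-fold to 333 ± 5.357 CPM. All 4 phenylalanine ammonia-lyase genes tested were higher, a grouping chosen after the values were seen. The 2 members that fell were the cinnamate 4-hydroxylase CYP73A14 (evm.TU.Ft8.4110, log2 change -1.44) and the 4-coumarate CoA ligase evm.TU.Ft5.1098 (-0.70).

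The list of flavonol pathway enzymes did not pass against all other genes at 2 h, with a median log2 change of 0.28: 12 of 28 tested genes were higher and 8 lower (camera adjusted p = 0.713). By enzyme step, a grouping chosen after the values were seen, 6 of 9 chalcone synthase genes were higher and 1 lower. CHS2 (evm.TU.Ft3.228) rose from 5.001 ± 1.20 to 9.49 ± 2.07 CPM and the more abundant CHS (evm.TU.Ft3.2401) from 323 ± 17.6 to 393 ± 11.1 CPM. Of the flavonoid 3'-hydroxylase genes annotated CYP75B137, evm.TU.Ft3.39 rose 1.60-fold and evm.TU.Ft3.40 fell by 0.63 on the log2 scale. Among glycosyltransferases and rhamnose genes of the flavonol glycosylation list, 5 of 21 tested genes were higher and 8 lower (camera adjusted p = 0.392). The rhamnosyltransferase RT (evm.TU.Ft4.2408) rose 1.24-fold, while GT5 (evm.TU.Ft7.2733) fell from 2.32 ± 0.252 to 0.133 ± 0.0376 CPM. In the anthocyanin and proanthocyanidin list 3 of 7 tested genes were higher and 0 lower (0.553), with LAR (evm.TU.Ft3.2588) up 2.10-fold and ANR (evm.TU.Ft8.1358) up 1.94-fold. Lignin genes rose as a list, with 32 of 69 higher and 15 lower (camera adjusted p = 0.0108), a call lost at adjusted p = 0.2001 with an estimated correlation. Its members include the laccase LAC9 (evm.TU.Ft5.991), up 12.8-fold, and HST (evm.TU.Ft2.76), the hydroxycinnamoyltransferase, down to 73.5 ± 1.64 from 155 ± 6.36 CPM.

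Of 129 MYB genes tested, 36 were higher and 33 lower at 2 h (camera adjusted p = 0.809). MYB78 (evm.TU.Ft5.998) went from 0.0639 ± 0.0161 to 3.57 ± 0.170 CPM, MYB102 (evm.TU.Ft3.1602) rose 5.54-fold, MYB306 (evm.TU.Ft1.2317) 3.57-fold and MYB62 (evm.TU.Ft1.489) 2.66-fold. MYB73 (evm.TU.Ft3.5601) reached 289 ± 0.750 from 122 ± 1.85 CPM, and the gene annotated MYB1R1, evm.TU.Ft8.2540, fell to 22.2 ± 0.982 from 44.7 ± 2.54 CPM. The 17 tested genes of MYB subgroups known for flavonoid control, all of them also among the 129, had 4 higher and 5 lower (0.870). MYB12 is an activator of flavonol synthesis genes in Arabidopsis: the MYB12 gene evm.TU.Ft1.1742 fell from 2.49 ± 0.151 to 0.387 ± 0.128 CPM, and the other, evm.TU.Ft5.363, stood at 3.30 ± 1.11 and 2.92 ± 0.466 CPM without passing the test. MYB4 (evm.TU.Ft5.2593), annotated as a repressor, fell by 0.50 and MYB5 (evm.TU.Ft2.1616) rose by 0.39 on the log2 scale. The falls of MYB6 (evm.TU.Ft5.2098, -0.39) and of the MYB4 gene evm.TU.Ft6.1649 (-0.20) were no longer called without 1 control library each, replicate 1 for MYB6 (-0.18) and replicate 2 for MYB4 (-0.13), nor was the latter without 2 h replicate 1 (-0.18). Among bHLH and WD40 partners of MYB factors, 3 of 8 were higher and 2 lower (0.771), with TTG1 (evm.TU.Ft3.2198) up 1.73-fold.

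ABA genes rose as lists: 9 of 20 metabolism genes were higher and 6 lower (camera adjusted p = 7.08e-06, 0.0169 with an estimated correlation), and 25 of 43 signalling genes were higher and 11 lower (3.80e-19, 0.0153 with an estimated correlation). A second NCED1 gene, evm.TU.Ft1.433, rose 65.4-fold and CYP707A2 (evm.TU.Ft2.5976), an ABA 8'-hydroxylase that degrades the hormone, 7.34-fold. The phosphatases ABI1 (evm.TU.Ft6.1992) and PP2CA (evm.TU.Ft7.219) rose 21.5-fold and 24.7-fold. By protein class, chosen after the values were seen, 7 of 11 ABA receptor genes were lower and 3 higher, against 7 of 10 protein phosphatase 2C genes higher and 9 of 12 SnRK2 kinase genes higher. Late embryogenesis abundant and dehydrin genes, whose products accumulate in drying tissue, had 19 of 27 higher and 2 lower (3.62e-14, 8.18e-04 with an estimated correlation), with the abundant COR410 (evm.TU.Ft2.6574) going from 125 ± 5.38 to 1401 ± 57.4 CPM and LEA5-A (evm.TU.Ft1.1300) from 89.7 ± 3.225 to 1073 ± 20.1 CPM. Osmoprotectant genes had 23 of 48 higher and 12 lower (0.00197, 0.0178 with an estimated correlation). Here the beta-amylase BAM1 (evm.TU.Ft7.5172) rose 4.93-fold. Genes that remove reactive oxygen had 44 of 93 higher and 26 lower (0.00488, 0.0345 with an estimated correlation), with glutathione S-transferase GSTU9 (evm.TU.Ft5.836) up 11.05-fold.

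Stress transcription factors rose in 4 of the 5 families listed. AP2/ERF genes had 58 of 110 higher and 22 lower (camera adjusted p = 7.03e-05, 0.0153 with an estimated correlation), NAC genes 34 of 62 and 16 (3.66e-07, 0.00303), WRKY genes 35 of 72 and 17 (8.11e-04, 0.0165) and heat stress factors 22 of 32 and 5 (2.26e-11, 0.00125), with the estimated correlation second in each pair. HD-ZIP genes had 12 of 46 higher and 17 lower and did not pass (0.535). ERF011 (evm.TU.Ft3.5567) reached 345 ± 8.89 from 66.6 ± 1.86 CPM, the NAC genes JA2L (evm.TU.Ft2.5584) and NAC048 (evm.TU.Ft3.4746) rose 27.2-fold and 7.11-fold, and WRKY60 (evm.TU.Ft8.363) and WRKY70 (evm.TU.Ft2.4587) rose 23.5-fold and 5.85-fold. HSFA2C (evm.TU.Ft6.1491) went from 41.0 ± 0.628 to 532 ± 11.7 CPM and HSFB4 (evm.TU.Ft7.4234) rose 22.8-fold, and the HD-ZIP genes HOX22 (evm.TU.Ft7.3765) and ATHB-40 (evm.TU.Ft7.2745) rose 8.41-fold and 10.4-fold. Heat shock protein genes had 50 of 85 higher and 13 lower (2.49e-04), a call lost at adjusted p = 0.137 with an estimated correlation. HSP17.4B (evm.TU.Ft6.1868) rose 7.93-fold. The rise of HSP70-2 (evm.TU.Ft5.547, 0.07) was lost without control replicate 2 (0.06) or without 2 h replicate 2 or 3 (0.07 in each case).

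The photosynthesis lists fell at 2 h, with 22 of 23 light-harvesting genes lower and 0 higher (camera adjusted p = 5.30e-11), 33 of 35 photosystem and electron transport genes lower and 0 higher (1.14e-15), 15 of 18 Calvin cycle genes lower and 1 higher (8.55e-11) and 19 of 26 chlorophyll synthesis genes lower and 4 higher (2.50e-07). With an estimated correlation the adjusted p were 0.203, 0.152, 0.0584 and 0.0548, so none of these 4 calls held under it. Rubisco activase RCA1 (evm.TU.Ft5.2681) fell from 14309 ± 608 to 5619 ± 172 CPM and HEMA1 (evm.TU.Ft4.5998), the glutamyl-tRNA reductase of chlorophyll synthesis, from 251 ± 14.7 to 73.1 ± 3.99 CPM. In the same libraries LHY (evm.TU.Ft5.2081), a morning-expressed clock gene, fell from 1272 ± 13.2 to 357 ± 4.07 CPM. The clock list itself had 17 of 27 higher and 8 lower (0.364).

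Auxin response genes fell, with 56 of 89 lower and 24 higher (camera adjusted p = 8.11e-04), a call lost at adjusted p = 0.138 with an estimated correlation. Cell wall expansion genes fell too, with 56 of 129 lower and 34 higher (0.0190), lost at adjusted p = 0.0607 with an estimated correlation. The estimate for cell wall expansion (0.00676) lay below the preset 0.01, so this loss does not come from a higher correlation between genes. AIR12 (evm.TU.Ft2.249) and GH3.10 (evm.TU.Ft8.3672) of the auxin list fell to 24.6 ± 0.9895 from 77.5 ± 4.54 and to 31.9 ± 1.33 from 67.99 ± 4.24 CPM. The jasmonate list (21 of 40 higher, 9 lower) missed the threshold at 0.0509 and passed it without 2 h replicate 1 (0.0330), 2 (0.0251) or 3 (0.0469) and without 8 h replicate 1 (0.0460) or 3 (0.0476). Lists without a call were gibberellin metabolism (3 of 9 higher, 5 lower, 0.870), cytokinin (13 of 37, 17 lower, 0.392), ethylene synthesis (5 of 10, 3 lower, 0.895), aquaporins (10 of 32, 16 lower, 0.163), cytosolic ribosome (76 of 267, 39 lower, 0.987) and cell cycle and histones (52 of 173, 33 lower, 0.905). Tissue marker lists did not pass either: root (3 of 23, 12 lower, 0.179), seed storage (8 of 13, 2 lower, 0.349), secondary wall and vascular (14 of 36, 4 lower, 0.708), epidermis and cuticle (26 of 99, 45 lower, 0.758) and organelle-encoded genes (3 of 15, 0 lower, 0.905).

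At 2 h all 3 treated libraries lay beyond all 3 controls for 65.9% of all genes tested, where chance gives 10%. This separation held for 95.4% of all genes called, which largely follows from the call on the same libraries. Named genes were chosen in part by this separation, and those called without it were FLA11 (evm.TU.Ft3.803, -0.39) and the LAR gene evm.TU.Ft6.2502 (0.45). Without single libraries the call of the first was lost at -0.24 (control replicate 3), -0.36 and -0.29 (2 h replicates 1 and 2), and that of the second at 0.41 and 0.42 (control replicates 1 and 2) and 0.41 and 0.34 (2 h replicates 2 and 3). Without single libraries calls at 2 h were also lost for RPL35AA (evm.TU.Ft8.2990, -0.09 and -0.12 without control replicates 1 and 2, -0.12 and -0.10 without 2 h replicates 2 and 3) and for the oleosin gene evm.TU.Ft8.2523 (0.47 and 0.46 without control replicate 2 and 2 h replicate 3), and the vicilin gene evm.TU.Ft4.4147 was called only without 2 h replicate 2 (-0.44). Median, mean and camera direction differed in sign for 7 lists: medians were negative and the direction upward for the anthocyanin, MYB and HD-ZIP lists, the mean alone was positive for the flavonoid MYB subgroups, and the direction alone was downward for ethylene synthesis, ribosome and cell cycle. Adjusted over the list alone, the counts equalled those over all genes except for heat shock proteins (51 higher), AP2/ERF (60 higher), jasmonate (22 higher), auxin (25 higher, 57 lower), cell wall expansion (57 lower), clock (9 lower), ribosome (67 higher, 36 lower), secondary wall (13 higher) and organelle-encoded genes (2 higher). Under another scaling or filter the median changed sign for the anthocyanin (-0.02 to 0.45), gibberellin (-0.32 to 0.57), MYB (-0.01 to 0.04) and seed storage (-0.16 to 1.08) lists.

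**Figure D2:**
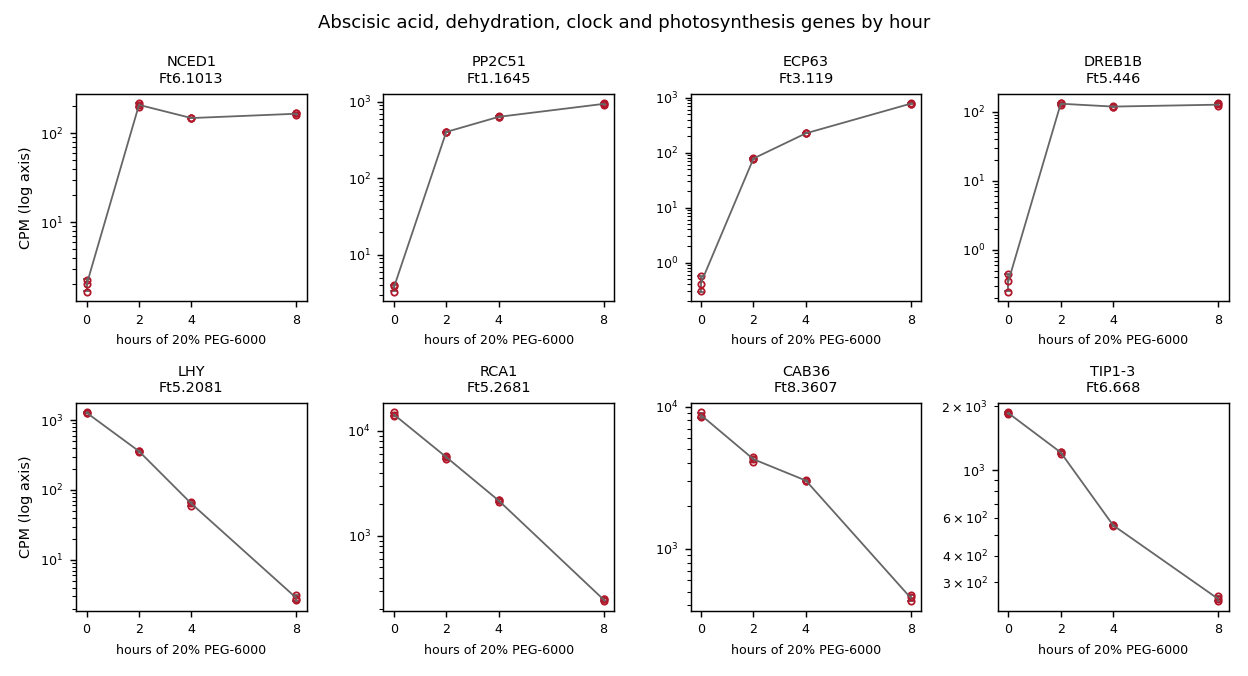
Levels in CPM (log axis) of 8 genes of abscisic acid synthesis and signalling, dehydration response, clock, photosynthesis and water transport against hours of 20% PEG-6000, with circles for single libraries and grey lines for the mean with SD (n = 3). NCED1 stands at 1.98 CPM at 0 h and 209 CPM at 2 h, and LHY at 1272 CPM at 0 h and 2.85 CPM at 8 h.

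After 4 h in PEG, late embryogenesis genes had risen further, Calvin cycle genes had fallen further, and most genes for cytosolic ribosomal proteins and aquaporins were lower than in the control. ECP63 (evm.TU.Ft3.119) of the late embryogenesis list stood at 226 ± 1.72 CPM against 0.428 ± 0.135 CPM (n = 3 each), 523-fold. The aquaporin TIP1-3 (evm.TU.Ft6.668) of the vacuolar membrane fell from 1855 ± 13.8 to 554 ± 2.60 CPM, and TIP1-1 (evm.TU.Ft6.205) from 1333 ± 70.3 to 196 ± 3.96 CPM. RPL23A (evm.TU.Ft7.1037), a ribosomal protein gene, fell from 61.5 ± 2.37 to 24.3 ± 0.868 CPM.

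At 4 h, too, rises and falls were ranked only among genes that met the rule for named genes. Genes that joined the 6 largest rises at 4 h were evm.TU.Ft3.2126, annotated as berberine bridge enzyme-like (0.556 ± 0.0843 to 280.4 ± 7.68 CPM, log2 change 8.97, SE 0.0973), STO-A (evm.TU.Ft2.5825), annotated as 11-beta-hydroxysteroid dehydrogenase A (101 ± 2.23 CPM, 364-fold), and LPPE2 (evm.TU.Ft2.4828), a plastid lipid phosphatase (103 ± 2.87 CPM, 337-fold). EDL3 (evm.TU.Ft7.3497, 399.5-fold) and DREB1B (evm.TU.Ft5.446, 338-fold) were again among them. The 6 largest falls held TPS8 (evm.TU.Ft3.1285, 0.0903 ± 0.0527 CPM left), LAC14 (evm.TU.Ft1.512, 0.150 ± 0.0502 CPM) and LOX2.1 (evm.TU.Ft2.1281, 3.39 ± 1.24 CPM), as at 2 h. Newly in this set were the adenosine kinase ADK (evm.TU.Ft2.3699, 39.1 ± 2.01 to 0.692 ± 0.133 CPM), evm.TU.Ft6.969, annotated as a kaempferol 3-O-galactosyltransferase (120.0 ± 5.51 to 3.954 ± 0.847 CPM), and the dehydrogenase GAPN (evm.TU.Ft8.359, 177 ± 13.6 to 6.99 ± 0.977 CPM). The largest adjusted p among these 12 genes was 1.74e-28 (edgeR).

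In the phenylpropanoid entry list 9 of 11 genes were higher and 2 lower at 4 h, and the list missed the threshold (camera adjusted p = 0.180). PAL3 stood at 131 ± 3.51 CPM (2.42-fold) and PAL (evm.TU.Ft6.641) at 135 ± 5.85 CPM (1.17-fold), and the ligase gene evm.TU.Ft5.1098 fell to 11.6 ± 0.374 CPM. Flavonol pathway genes went both ways, 10 of 28 higher and 10 lower (0.880), with CHS2 evm.TU.Ft3.228 up 2.24-fold and the flavanone 3-hydroxylase gene evm.TU.Ft8.3108 down to 14.5 ± 0.797 from 26.2 ± 3.47 CPM. The glycosylation list had 4 of 21 higher and 10 lower (0.376). GT3 (evm.TU.Ft5.733) fell to 5.54 ± 0.449 from 24.1 ± 2.12 CPM, GT4 (evm.TU.Ft7.4533) to 8.30 ± 0.548 from 23.2 ± 2.99 CPM, and the rhamnose transporter URGT4 (evm.TU.Ft7.4873) rose 1.45-fold. The rise of the GT3 gene evm.TU.Ft5.572 (0.90) was lost without control replicate 2 (0.77) or 4 h replicate 2 (0.77). In the anthocyanin and proanthocyanidin list 1 of 7 genes was higher and 3 lower (0.905): LAR evm.TU.Ft3.2588 (-0.50), ANR (-0.26) and DFR (evm.TU.Ft4.5802, -0.23) fell, and the putative anthocyanidin reductase evm.TU.Ft3.2909 rose 1.87-fold. Lignin genes had 35 of 69 higher and 14 lower and missed the threshold at 0.0590, passing it without 2 h replicate 2 (0.0480) or 4 h replicate 2 (0.0495). LAC9 reached 207 ± 5.38 CPM, 48.8-fold.

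MYB genes had 48 of 129 higher and 32 lower at 4 h (camera adjusted p = 0.758), and the flavonoid subgroups 8 of 17 higher and 2 lower (0.923). MYB78 rose 143-fold to 9.61 ± 1.12 CPM, MYB306 to 118 ± 4.20 CPM and MYB62 to 131 ± 5.75 CPM. The MYB12 gene evm.TU.Ft1.1742 was down to 0.161 ± 0.0522 CPM. The fall of the other, evm.TU.Ft5.363 (-0.60), was lost without control replicate 1 (-0.30). MYB6 (0.07) was called, at 0.28, without control replicate 1, and the MYB4 gene evm.TU.Ft6.1649 (-0.16) was called without control replicate 3 (-0.22), 4 h replicate 1 (-0.21) or 8 h replicate 2 (-0.16). The bHLH and WD40 partners had 5 of 8 higher and 1 lower (0.716), with TTG1 at 89.2 ± 5.30 CPM.

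The stress lists stayed up at 4 h, each below with the camera adjusted p and then that with an estimated correlation. ABA metabolism had 12 of 20 genes higher and 5 lower (3.87e-04, 0.0280), ABA signalling 25 of 43 and 12 (1.16e-14, 0.0178) and late embryogenesis 21 of 27 and 1 (1.13e-14, 8.18e-04). Osmoprotectants had 26 of 48 higher and 16 lower (0.00116, 0.0178) and reactive oxygen removal 49 of 93 and 26 (2.86e-04, 0.0169). AP2/ERF had 59 of 110 higher and 29 lower (0.00311, 0.0290), NAC 34 of 62 and 16 (2.10e-05, 0.00659), WRKY 40 of 72 and 15 (0.00918, 0.0260) and heat stress factors 25 of 32 and 5 (4.42e-06, 0.00706). The raffinose synthase genes RFS6 (evm.TU.Ft6.3528) and RFS1 (evm.TU.Ft5.1181) rose to 2236 ± 42.6 and 816 ± 5.0 CPM from 807 ± 15.01 and 139.7 ± 8.58 CPM. Glutathione S-transferases GSTU8 (evm.TU.Ft7.771) and GSTU18 (evm.TU.Ft1.266) rose 17.2-fold and 4.15-fold, WRKY33 (evm.TU.Ft8.948) 3.81-fold, DREB2C (evm.TU.Ft5.2361) 16.2-fold and a second JA2L gene, evm.TU.Ft2.3431, 7.41-fold. HD-ZIP (17 of 46 higher, 18 lower, 0.566), heat shock (44 of 85, 22 lower, 0.693) and jasmonate (18 of 40, 15 lower, 0.102) lists did not pass, although the jasmonate synthesis genes OPR11 (evm.TU.Ft6.1317) and AOC4 (evm.TU.Ft2.5776) rose 325-fold and 23.1-fold.

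Cytosolic ribosomal protein genes fell at 4 h: 250 of 267 were lower and 4 higher, with a median log2 change of -0.54 (camera adjusted p = 2.26e-11). That call was lost at adjusted p = 0.323 with an estimated correlation. RPL35AA (evm.TU.Ft8.2990) fell from 72.9 ± 2.16 to 33.9 ± 0.877 CPM, and evm.TU.Ft1.2832, whose description reads L18a-like, rose to 267 ± 4.94 from 134 ± 3.45 CPM. Aquaporins fell, with 25 of 32 lower and 4 higher (4.14e-08, 0.0345 with an estimated correlation), as did cell wall expansion genes, with 73 of 129 lower and 31 higher (0.00128, 0.0280 with an estimated correlation). EXPA8 (evm.TU.Ft1.760), an expansin, fell from 543 ± 9.54 to 83.9 ± 2.80 CPM, while the pectinesterase PECS-2.1 (evm.TU.Ft1.2870) rose to 196 ± 7.30 from 20.6 ± 0.446 CPM. Auxin response genes had 56 of 89 lower and 23 higher (0.00430), a call lost at adjusted p = 0.208 with an estimated correlation. In the photosynthesis lists 21 of 23 light-harvesting genes were lower and 1 higher (1.09e-09), 32 of 35 photosystem genes lower and 0 higher (2.66e-16), 16 of 18 Calvin cycle genes lower and 1 higher (2.55e-20) and 18 of 26 chlorophyll synthesis genes lower and 3 higher (4.85e-09). With an estimated correlation the light-harvesting and photosystem calls were lost (adjusted p = 0.249 and 0.152) and the Calvin cycle and chlorophyll calls held (0.0178 and 0.0384). The phosphoribulokinase evm.TU.Ft2.692 fell from 1741 ± 58.2 to 250.0 ± 6.667 CPM, and LHY evm.TU.Ft5.2081 fell to 63.6 ± 4.57 CPM in the same libraries.

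No call was made at 4 h for ethylene synthesis (4 of 10 higher, 5 lower, camera adjusted p = 0.237), gibberellin metabolism (2 of 9, 4 lower, 0.766), cytokinin (11 of 37, 20 lower, 0.234), clock (14 of 27, 9 lower, 0.841) or cell cycle genes (32 of 173, 82 lower, 0.179). Nor was there one for root (4 of 23, 10 lower, 0.166), seed storage (9 of 13, 2 lower, 0.0920), secondary wall (13 of 36, 5 lower, 0.708), epidermis (33 of 99, 46 lower, 0.862) or organelle-encoded genes (10 of 15, 0 lower, 0.758). Single members of these lists still moved far. The ethylene synthesis gene ACS1 (evm.TU.Ft5.2150) rose 27.5-fold while the oxidases ACO3 (evm.TU.Ft8.3626) and ACO1 (evm.TU.Ft2.6493) fell to 194 ± 3.46 from 871 ± 17.6 and to 443 ± 17.8 from 1071 ± 26.0 CPM. GA20OX2 (evm.TU.Ft8.2628), of gibberellin synthesis, fell to 1.82 ± 0.279 from 13.5 ± 1.22 CPM and GA2OX2 (evm.TU.Ft1.1761), of gibberellin breakdown, rose 4.23-fold. Cytokinin response regulators ARR4 (evm.TU.Ft6.858) and ARR9 (evm.TU.Ft5.1613) fell to 15.4 ± 0.734 and 2.63 ± 0.350 CPM, the root patterning genes SHR (evm.TU.Ft1.1106) and SCR (evm.TU.Ft3.280) to 2.95 ± 0.458 and 12.4 ± 1.23 CPM, and the kinesin KIN13B (evm.TU.Ft4.3167) to 22.1 ± 0.408 CPM. Of 3 organelle genes named ycf68-2, at most 1.40 CPM on average in any group, the rise of evm.TU.HiC_scaffold_5.97 rested on 4 h replicate 3 (log2 change 4.22 with it and 2.17, not called, without it), and at 8 h it was called without 4 h replicate 1 (2.28) or 3 (2.28) or 8 h replicate 1 (2.59).

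All 3 treated libraries lay beyond all 3 controls for 74.4% of genes tested at 4 h (10% by chance). The share was 96.4% among genes called, which were selected on the same libraries. Named genes called without this separation were ANR and the ycf68-2 gene evm.TU.HiC_scaffold_5.97. Median, mean and camera direction differed in sign for the flavonol pathway (mean positive, direction downward), the flavonoid MYB subgroups (mean negative, direction upward) and the epidermis list (median and mean negative, direction upward). Adjusted over the list alone, counts differed from those over all genes for MYB genes (47 higher, 31 lower), reactive oxygen removal (27 lower), cell wall expansion (32 higher), ribosome (252 lower) and cell cycle (30 higher). List medians changed sign under another scaling or filter for cytokinin (-0.53 to 0.06), HD-ZIP (-0.03 to 0.06) and jasmonate (-0.03 to 0.12). The median of all genes was -0.04 under TMM and -0.10 under library-size scaling. Not called at 0.32, CESA8 (evm.TU.Ft8.5098) was called without control replicate 3 (0.37), 2 h replicate 3 (0.32) or 4 h replicate 1 (0.41).

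**Figure D3:**
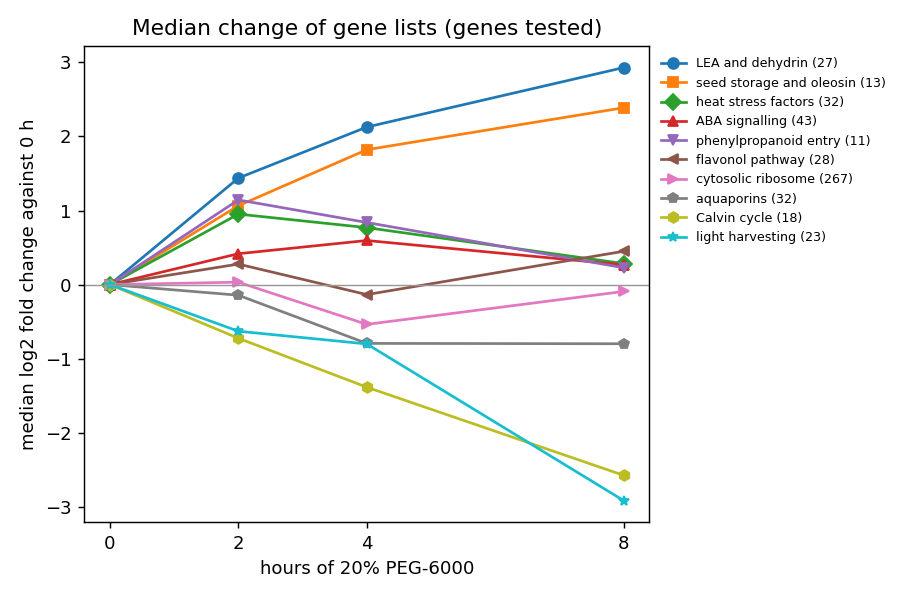
Median log2 fold change against 0 h (vertical axis) of 10 gene lists, with the number of genes tested in parentheses, against hours of 20% PEG-6000 (horizontal axis). The late embryogenesis line rises to 2.93 at 8 h, the ribosome line dips to -0.54 at 4 h, and the light-harvesting line reaches -2.92 at 8 h.

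After 8 h in PEG, most chalcone synthase and anthocyanidin pathway genes stood above the control, late embryogenesis and seed storage genes were higher, and photosynthesis genes were lower. The median fall of light-harvesting and Calvin cycle genes was deeper than at 2 or 4 h. CHS2 (evm.TU.Ft3.228) rose from 5.001 ± 1.20 to 60.6 ± 2.43 CPM (n = 3 each), 12.1-fold, and FLS (evm.TU.Ft5.635) from 24.9 ± 0.896 to 78.1 ± 3.48 CPM. Of 3 flavonol synthase genes, however, 1 was higher and 2 lower. Neither the flavonol pathway nor the anthocyanin list passed against all other genes (camera adjusted p = 0.377 and 0.214). ECP63 reached 785 ± 22.8 CPM, 1816-fold. RCA1 (evm.TU.Ft5.2681), the activase of the carbon-fixing enzyme Rubisco, fell from 14309 ± 608 to 247 ± 7.61 CPM, and LHY evm.TU.Ft5.2081 from 1272 ± 13.2 to 2.85 ± 0.287 CPM.

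Rises and falls at 8 h were ranked only among genes that met the rule for named genes, as at 2 h. The 6 largest rises at 8 h were those of STO-A (evm.TU.Ft2.5825, 0.274 ± 0.10 to 694 ± 23.1 CPM, log2 change 11.29, SE 0.0820), the reticulon RTNLB13 (evm.TU.Ft4.4708, 112.96 ± 11.3 CPM, from 5 counts over the 3 control libraries), ECP63, LT101.2 (evm.TU.Ft2.2832), a low temperature-induced protein (149 ± 6.15 CPM, 1575-fold), the seed maturation gene GMPM1 (evm.TU.Ft1.1425, 232 ± 7.96 CPM, 1042-fold) and SWEET14 (59.1 ± 1.41 CPM, 484-fold). The 6 largest falls were those of both LHY genes, the second being evm.TU.Ft7.3783 (368 ± 7.19 to 2.34 ± 0.108 CPM), of COL2 (evm.TU.Ft5.2569) and a neighbour in number, COL2 evm.TU.Ft5.2570 (57.2 ± 0.895 to 0.194 ± 0.127 and 52.3 ± 4.54 to 0.323 ± 0.282 CPM), of the thylakoid protein gene PPD7 (evm.TU.Ft4.3541, 57.2 ± 2.26 to 0.193 ± 0.124 CPM) and of CYP736A117 (evm.TU.Ft2.5766), a cytochrome P450 (41.3 ± 1.84 to 0.146 ± 0.0391 CPM). The largest adjusted p among these 12 genes was 6.98e-32 (edgeR).

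Flavonol pathway genes had 14 of 28 higher and 11 lower at 8 h, with no call for the list (camera adjusted p = 0.377). The steps parted: 7 of 9 chalcone synthase genes were higher and 1 lower (median log2 change 1.11, and 1.27 under library-size scaling), and 6 of 8 flavonoid 3'- and 3',5'-hydroxylase genes were lower and 1 higher (median -0.88, and -0.73 with 5 lower under library-size scaling), a grouping chosen after the values were seen. CHS evm.TU.Ft3.2401 reached 699 ± 31.3 CPM (2.17-fold), and CYP75B137 evm.TU.Ft3.40 and evm.TU.Ft3.39 fell to 44.8 ± 2.69 and 79.1 ± 3.62 CPM. The flavanone 3-hydroxylase gene evm.TU.Ft8.3108, below the control at 4 h, stood at 62.2 ± 3.31 CPM (2.38-fold). Of 3 flavonol synthase genes 1 was higher and 2 lower, or 1 and 1 under library-size scaling (median -0.20, and -0.05 under that scaling). In the anthocyanin and proanthocyanidin list 6 of 7 genes were higher and 0 lower, with no call for the list (0.214): LAR evm.TU.Ft3.2588 rose 2.44-fold, ANR 2.17-fold, LAR evm.TU.Ft6.2502 1.84-fold, DFR 1.158-fold and the acyltransferase evm.TU.Ft8.65 1.81-fold. The glycosylation list had 5 of 21 higher and 10 lower (0.784), with RT at 140.0 ± 5.78 CPM (3.56-fold), GT3 evm.TU.Ft5.572 up 7.92-fold and GT3 evm.TU.Ft5.733 down to 4.30 ± 0.398 CPM. Phenylpropanoid entry genes had 7 of 11 higher and 2 lower (0.776), PAL evm.TU.Ft6.641 rising 2.06-fold and CYP73A14 falling to 9.61 ± 1.35 CPM. 4CL1, at 37.7 ± 2.10 CPM and a log2 change of -0.10, was not called, but was called without control replicate 2 (-0.14) or 8 h replicate 1 (-0.15). Lignin genes had 27 of 69 higher and 21 lower (0.879), and HST fell to 20.8 ± 0.610 CPM.

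**Figure D4:**
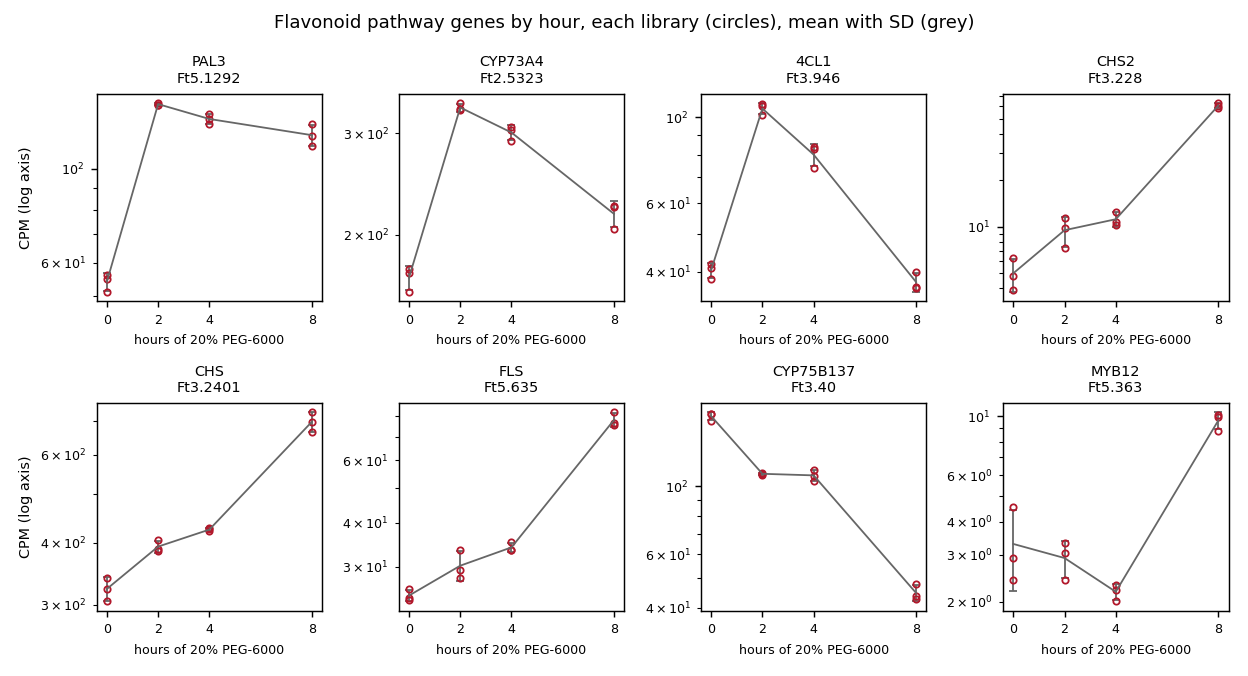
Levels in CPM (log axis) of 8 phenylpropanoid, flavonol and MYB genes against hours of 20% PEG-6000, with circles for single libraries and grey lines for the mean with SD (n = 3). PAL3 lies at 142 CPM at 2 h and 120.0 CPM at 8 h, and CHS2 at 9.49 CPM at 2 h and 60.6 CPM at 8 h.

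MYB genes had 52 of 129 higher and 36 lower at 8 h (camera adjusted p = 0.433), and the flavonoid subgroups 11 of 17 higher and 2 lower (0.392), with a median log2 change of 0.66. MYB12 evm.TU.Ft5.363 rose from 3.30 ± 1.11 to 9.62 ± 0.709 CPM (2.92-fold) and MYB12 evm.TU.Ft1.1742 fell to 0.309 ± 0.105 CPM. MYB6 rose 1.97-fold, MYB5 1.96-fold and MYB4 evm.TU.Ft6.1649 1.38-fold. MYB4 evm.TU.Ft5.2593 did not pass at -0.00, while under library-size scaling it was called at 0.15. MYB78 reached 24.2 ± 2.83 CPM (358-fold), MYB102 36.4 ± 3.64 CPM and MYB306 159 ± 12.7 CPM. The bHLH and WD40 partners had 7 of 8 higher and 1 lower (0.352), with GL3 (evm.TU.Ft1.1874) up 3.69-fold and BHLH42 (evm.TU.Ft1.1211) 1.88-fold. The small rise of TTG1 (0.12) was lost without control replicate 1 (0.08) or 2 (0.12) or 8 h replicate 1 (0.11) or 2 (0.10), and with DESeq2 size factors (0.10).

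Light-harvesting genes fell at 8 h to a median log2 change of -2.92, 22 of 23 lower and 0 higher (camera adjusted p = 9.17e-59, 0.0165 with an estimated correlation). Photosystem genes had 34 of 35 lower and 0 higher (3.02e-42, 0.0316), Calvin cycle genes 16 of 18 lower and 1 higher (1.70e-45, 0.00596) and chlorophyll synthesis genes 18 of 26 lower and 4 higher (1.13e-14, 0.0178), with the estimated correlation second in each pair. LHCB5 (evm.TU.Ft3.2698) fell from 4283 ± 216 to 133 ± 2.82 CPM, CAB36 to 451 ± 21.7 CPM, PSBS (evm.TU.Ft2.3625) from 638 ± 27.4 to 27.2 ± 1.98 CPM, GAPB (evm.TU.Ft4.6068) from 1824 ± 76.2 to 148 ± 5.32 CPM and CHLH (evm.TU.Ft7.2841) from 1649.8 ± 108 to 48.2 ± 2.43 CPM. The clock list fell in the same libraries, with 14 of 27 lower and 11 higher (0.0103), a call lost at adjusted p = 0.159 with an estimated correlation, and LNK2 (evm.TU.Ft2.6184) went from 377 ± 7.997 to 21.8 ± 1.07 CPM. Aquaporins fell, with 21 of 32 lower and 10 higher (4.90e-06), a call lost at adjusted p = 0.0662 with an estimated correlation. TIP1-3 was down to 251 ± 6.42 CPM and PIP2-2 (evm.TU.Ft2.2721) to 83.6 ± 5.78 from 474 ± 12.5 CPM. Cell wall expansion genes fell, with 66 of 129 lower and 34 higher (0.0413), a call lost at adjusted p = 0.146 with an estimated correlation and without 8 h replicate 1 (0.0509) or 3 (0.0551), while XTHB (evm.TU.Ft1.2575) rose 5.77-fold.

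Late embryogenesis genes rose again, with 24 of 27 higher and 1 lower (camera adjusted p = 9.02e-21, 5.09e-04 with an estimated correlation), and so did ABA signalling genes, with 24 of 43 higher and 14 lower (1.30e-14, 0.0178 with an estimated correlation). PP2C51 stood at 938 ± 24.2 CPM, 252-fold, and 8 of 11 ABA receptor genes were lower. ABA metabolism had 10 of 20 higher and 7 lower (0.0108), lost at adjusted p = 0.0743 with an estimated correlation. Heat stress factors (17 of 32 higher, 6 lower, 1.22e-04) and NAC genes (28 of 62 higher, 18 lower, 0.0155) held with an estimated correlation (0.0165 and 0.0345), and AP2/ERF (56 of 110 higher, 36 lower, 0.0174) and HD-ZIP genes (22 of 46 higher, 15 lower, 0.0211) did not (adjusted p = 0.0662 and 0.0595 with an estimated correlation). For AP2/ERF and HD-ZIP the estimates (0.00790 and 0.00275) lay below the preset 0.01, so a higher correlation does not account for these losses. HSFA6b (evm.TU.Ft7.5245) rose to 129 ± 4.85 CPM, 20.8-fold, and HOX22 evm.TU.Ft4.3904 12.4-fold. Lists of tissue markers also moved: seed storage and oleosin genes rose, with 9 of 13 higher and 3 lower (0.00357, 0.0345 with an estimated correlation), among them the vicilin gene LOC108986502 (evm.TU.Ft4.4147, 1.997 ± 0.154 to 95.1 ± 4.15 CPM) and the oleosin gene evm.TU.Ft8.2523 (0.603 ± 0.20 to 23.0 ± 2.01 CPM). Epidermis and cuticle genes rose (40 of 99 higher, 38 lower, 0.0190), as did secondary wall genes (24 of 36 higher, 3 lower, 0.0317). Both calls were lost with an estimated correlation (adjusted p = 0.323 and 0.273), and the secondary wall call also under library-size scaling (0.0517). CER26 (evm.TU.Ft5.1687) rose 131-fold, the wax gene CER1 (evm.TU.Ft5.2437) 33.4-fold, LTP1 (evm.TU.Ft2.4267) to 3245 ± 226 from 247 ± 6.68 CPM, FLA11 13.1-fold, CESA7 (evm.TU.Ft3.965) 11.1-fold and CESA8 9.57-fold.

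At 8 h no call was made for osmoprotectants (23 of 48 higher, 19 lower, camera adjusted p = 0.364), reactive oxygen removal (43 of 93, 37 lower, 0.649), heat shock proteins (45 of 85, 25 lower, 0.919), WRKY (23 of 72, 25 lower, 0.887) or jasmonate genes (17 of 40, 16 lower, 0.987). RFS6 and RFS1, above the control at 4 h, fell below it, to 404 ± 8.51 and 83.3 ± 9.41 CPM, as did GSTU9 (6.71 ± 1.30 CPM), GSTU18 (20.7 ± 1.02 CPM) and WRKY70 (17.8 ± 0.591 CPM). WRKY33 evm.TU.Ft8.948 did not pass at 0.01, and was called at 0.16 under library-size scaling and on FPKM. HSC80 (evm.TU.Ft8.2665) fell from 462 ± 7.78 to 135 ± 4.62 CPM, and LOX2.1, far below the control earlier, rose to 245 ± 17.6 CPM. Hormone lists without a call were auxin (25 of 89 higher, 51 lower, 0.0956), cytokinin (9 of 37, 22 lower, 0.0764), gibberellin (2 of 9, 5 lower, 0.976) and ethylene synthesis (4 of 10, 5 lower, 0.0634), the last passing without control replicate 2 (0.0495) or 3 (0.0370). GA2OX8 (evm.TU.Ft4.57) rose 21.7-fold and SAUR32 (evm.TU.Ft4.4922) 25.3-fold. Ribosome (33 of 267 higher, 128 lower, 0.533), cell cycle (73 of 173, 31 lower, 0.533), root (4 of 23, 12 lower, 0.378) and organelle-encoded lists (2 of 15, 0 lower, 0.818) did not pass.

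Of the calls at 8 h 51.4% were higher under TMM, but 62.5% under library-size scaling (10206 higher, 6124 lower) and 62.4% on FPKM. Library-size scaling moved the median log2 change of all genes from 0.03 to 0.18. At 8 h the same separation held for 72.8% of genes tested (10% by chance) and for 96.0% of genes called, which were selected on the same libraries. Named genes called without it were TTG1 and the peroxidase gene evm.TU.Ft3.3736. Median, mean and camera direction differed in sign for WRKY (mean negative) and jasmonate (mean negative), both with an upward direction. Adjusted over the list alone, counts differed for MYB genes (51 higher), ABA signalling (15 lower), osmoprotectants (24 higher), heat stress factors (7 lower), auxin (26 higher), ribosome (32 higher, 126 lower), cell cycle (72 higher, 30 lower), secondary wall (4 lower) and organelle-encoded genes (0 higher). The median changed sign under another scaling or filter for the clock (-0.35 to 0.01), ribosome (-0.11 to 0.06), ethylene (-0.51 to 0.53) and WRKY (-0.01 to 0.15) lists.

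Between 2 and 4 h, genes for aquaporins and Calvin cycle enzymes fell and late embryogenesis genes rose. In all, 11729 genes differed (5803 higher and 5926 lower at 4 h, edgeR). In the ribosome list 252 of 267 genes were lower at 4 h and 3 higher (camera adjusted p = 1.11e-44, and adjusted p = 0.0802 with an estimated correlation, where the call was lost). Aquaporins (22 of 32 lower, 5 higher, 4.52e-19), Calvin cycle genes (16 of 18 lower, 1 higher, 1.82e-21) and late embryogenesis genes (18 of 27 higher, 2 lower, 4.81e-06) held with an estimated correlation (0.0199, 0.0227 and 0.0199). Light-harvesting (13 of 23 lower, 3 higher, 0.0214), photosystem (23 of 35 lower, 1 higher, 8.50e-06) and chlorophyll synthesis genes (15 of 26 lower, 2 higher, 3.84e-05) passed with the preset correlation alone (adjusted p = 0.658, 0.432 and 0.133 with an estimated correlation). PIP2-2, above the control at 2 h (679.8 ± 11.7 CPM), was at 138 ± 3.15 CPM at 4 h (log2 change -2.30, SE 0.0402), and PECS-2.1 rose from 40.02 ± 1.31 to 196 ± 7.30 CPM. LAR evm.TU.Ft3.2588 and ANR fell from 26.2 ± 1.54 to 8.77 ± 0.361 and from 62.7 ± 2.79 to 27.0 ± 3.15 CPM. Of the calls 49.5% were higher at 4 h under TMM and 37.1% under library-size scaling.

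Between 4 and 8 h, light-harvesting, Calvin cycle and WRKY genes fell and late embryogenesis genes rose. The test called 14445 genes (7452 higher and 6993 lower at 8 h, edgeR). Light-harvesting genes had 20 of 23 lower and 1 higher (camera adjusted p = 1.12e-62, 0.0223 with an estimated correlation), Calvin cycle genes 14 of 18 lower and 1 higher (6.34e-22, 0.0227), WRKY genes 42 of 72 lower and 8 higher (7.06e-04, 0.0216) and late embryogenesis genes 19 of 27 higher and 4 lower (4.74e-04, 0.0227). Ribosomal protein genes rose, 244 of 267 higher and 4 lower (1.51e-16), and anthocyanin and proanthocyanidin genes rose, 6 of 7 higher and 1 lower (0.0328). Both calls were lost with an estimated correlation (adjusted p = 0.262 and 0.133). The flavonol pathway had 13 of 28 higher and 7 lower and missed the threshold (0.0672). CHS2 evm.TU.Ft3.228 rose by 2.44 (SE 0.0993), FLS evm.TU.Ft5.635 by 1.20 and MYB12 evm.TU.Ft5.363 by 2.14 on the log2 scale, while 4CL1 fell by 1.09, MYB62 by 1.25 and LAC9 from 207 ± 5.38 to 4.17 ± 0.187 CPM. LPPE2, raised at 4 h, fell to 0.173 ± 0.0653 CPM. Of the calls 51.6% were higher at 8 h under TMM and 70.7% under library-size scaling, which moved the median of all genes from 0.04 to 0.26.

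A single test over the 3 PEG times called 19568 of 22063 genes as differing between any of the 4 times (edgeR). Genes higher than the control at all 3 times numbered 4244 and genes lower at all 3 times 4719, where independent lists of the same sizes would share 891 and 907. With the 2-fold minimum the counts were 1087 and 1323. NCED1 evm.TU.Ft6.1013 (148 ± 1.47 CPM at 4 h and 166 ± 3.46 CPM at 8 h), DREB1B, EDL3 and ABI1 are among the former and RCA1, CAB36, both ARR4 genes and GA20OX2 among the latter. Another 914 genes were higher at 2 h and lower at 8 h, and 562 lower at 2 h and higher at 8 h. Independent lists of the same sizes would share 2403 and 2544 genes in these opposite directions, so reversals were fewer than that. All of the reversed genes also differed between 2 and 8 h in the direct test, which nearly follows from opposite calls against the same controls. The 3 comparisons share the same 3 controls, too few to split. Part of the excess in the same direction, and of the shortfall in opposite directions, may come from them. In 10 simulations of unchanged genes a mean of 0 genes passed at all 3 times in either direction by edgeR, and 43.5 (higher) and 36.9 (lower) at an unadjusted p under 0.05. With no gene changed, a mean of only 0.133 genes was called per time, so the 0 does not measure the part due to shared controls. Over the 38 lists and 3 times against the control, 52 tests passed with the preset correlation and 32 with an estimated one, all 32 of them among the 52. Of 421 pairs of a named gene and a time, rule genes counted at the time they were named for and list genes at all 3 times, 394 were called. These genes were chosen by the same tests, so a high share follows from the choice.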

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

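The tests of normalization, green-cell share, time of day and seed material below were chosen only after the results were seen. Of 153 named genes, 142 had a called difference between their changes at 8 h and at 2 h (edgeR). Named genes were chosen for large changes or small p in these same data, so this share says little about other genes. Genes were flagged where the changes at 2 times were called with opposite signs and the direct test between those times called the difference (20 genes). The called difference is thus a condition of the choice and not a result. Groups of 3 libraries were not tested for outlying samples.

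Among flavonoid genes, the change at 8 h exceeded that at 4 h by 2.10 on the log2 scale for the flavanone 3-hydroxylase gene evm.TU.Ft8.3108, 1.79 for LAR evm.TU.Ft3.2588, 1.38 for ANR and 0.44 for DFR, and lay 1.20 below it for CYP75B137 evm.TU.Ft3.39 (-1.20). For MYB12 evm.TU.Ft5.363 the difference was 2.14. Against 2 h, the change at 8 h was higher by 1.37 for MYB6 and 0.66 for MYB4 evm.TU.Ft6.1649. All of these were called below the control at the earlier time of the pair and above it at 8 h, except CYP75B137, which went the other way. LAR and ANR had been above the control at 2 h. The falls of 3 genes were each lost without 1 control library: MYB12 evm.TU.Ft5.363 at 4 h (-0.30), MYB6 at 2 h (-0.18) and MYB4 evm.TU.Ft6.1649 at 2 h (-0.13).

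In stress and growth genes, the differences of 8 h from 4 h were 6.18 for LOX2.1, 4.47 for FLA11, -2.47 for RFS6, -3.29 for RFS1, -5.15 for GSTU9, -3.07 for GSTU18 and -6.13 for PECS-2.1. Those of 8 h from 2 h were 5.50 for MLP31, -2.09 for HSC80, -1.58 for HSP70-2, -3.15 for WRKY70 and -3.02 for PIP2-2. The small rise of HSP70-2 at 2 h (0.07) was lost without control replicate 2 or without 2 h replicate 2 or 3.

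The fall of the photosynthesis lists at 8 h is not a product of TMM, since the light-harvesting median was -2.76 under library-size scaling. A smaller share of green cells, as the whole cause, would lower these lists alike if their genes were expressed in green cells alone, which was not tested. The light-harvesting median lay 2.14 below that of chlorophyll synthesis (-2.14, permutation p = 5.30e-04, adjusted 0.00318). It lay 1.17 below that of the photosystem list (permutation p = 0.00221), and not apart from the Calvin cycle median (difference -0.34, permutation p = 0.318). The Calvin cycle median lay apart from those of chlorophyll synthesis (-1.80, adjusted permutation p = 0.00652) and the photosystem list (0.83, 0.0429), and the chlorophyll median ranged from -1.60 to -0.61 over settings. The permutations moved genes singly, although the estimated correlation between genes at 8 h was 0.686 for light harvesting and 0.144 for chlorophyll synthesis. Their p-values may therefore be too small. Of other tissue markers in this leaf and stem material, secondary wall genes (median 0.54) and epidermis genes (0.07) were called upward (adjusted p = 0.273 and 0.323 with an estimated correlation, where both calls were lost) and root genes (-0.41) were not called. A smaller green share as all or part of the cause stays open. LHY changed by -8.79 in the same libraries, so time of day could account for the fall as well as PEG could, and the series holds no untreated 8 h library to decide between them.

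Ribosomal protein genes were lower at 4 h under library-size scaling too (median -0.60). They have short coding sequences (median 459 against 1134 for other genes), so a bias with length or abundance was tested with a prediction written before its result. After the trend was removed the median was -0.87 (bootstrap range -0.93 to -0.84), against -0.54 before, so the trend is not the cause. LHY had changed by -4.32 at 4 h, and time of day could not be told from PEG.

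The rise of seed storage and oleosin genes at 8 h could come from seed material among the seedlings. If such material carried abundant 13S globulin transcripts, these would come with it. They stood at 0.329 CPM at 0 h and at 0.349 CPM at 8 h beside 121 CPM for vicilin, 0.287% of that level. No seed library was at hand to check the premise, so seed material without these transcripts is not excluded. The LHY change of -8.79 leaves time of day open for this rise, and the series holds no untreated library of that hour to test it.

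In random splits of the libraries, 1 of 100 (the real one) reached the 19568 genes called at any time, where the highest other split gave 15564. The same held for the overlap of calls between times (8963, highest other 6462, 1 of 100) and for the lists passed (52, highest other 51, 1 of 100). Random groups mix libraries of times that differ strongly, so these splits still hold real differences and do not stand for unchanged data. The count of lists, 52 against 51, hardly sets the real grouping apart. In fits of the 6 libraries of 2 groups, the real grouping gave 13693, 15835, 15471, 11671 and 14396 calls, and no other of the 10 splits gave any. The 10 splits (1 as large) are too few for a share under 0.05.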

How the results depend on the processing

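Library-size scaling and the alternatives for the overlap between times were chosen after the data were seen. Over all settings, named genes kept their side of the threshold, and the direction of any call, in 9126 cases. They gained a call in 26, lost it in 49 and reversed in 4. Where neither fit made a call, direction was not compared. By the same rule, lists kept their side of the threshold in 1859 cases, gained a call in 56 and lost it in 23. Counts stayed within 1.5 times in 188 cases and moved in 6. Without the fold minimum, alternatives gave 11028 to 14151 genes at 2 h, 12438 to 16418 at 4 h, 11947 to 16530 at 8 h, 9777 to 11950 for 4 against 2 h, 11299 to 16063 for 8 against 4 h, 14541 to 20451 at any time and an overlap of 7336 to 9032. With the 2-fold minimum, which removes small changes by construction, the counts were 4101, 5976 and 5957 at 2, 4 and 8 h and the overlap 2410. Of 421 pairs of a named gene and a time 394 were called, and 372 to 397 in the alternatives. Since named genes were chosen for large changes or small p in these data, their calls may be steadier than those of other genes. The 4 reversals concern MYB4 evm.TU.Ft5.2593 at 8 h, uncalled at -0.00: 0.149 on log2(FPKM + 1), 0.151 on log2(FPKM + 0.1), 0.149 on log2(FPKM + 1) without a filter and 0.147 under library-size scaling. These 4 settings lack TMM, and library-size scaling moved the median of all genes at 8 h from 0.03 to 0.18, about as far as this gene.

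Lists passing numbered 52 with the preset correlation, 32 with an estimated one and 99 by fry, which does not compare a list with other genes. By fry the adjusted p was 1.05e-04 at 2 h and 2.41e-06 at 8 h for the flavonol pathway, 6.38e-07 and 4.15e-09 for the anthocyanin list, 1.50e-08 at 4 h and 6.48e-04 at 8 h for phenylpropanoid entry, and 9.04e-04 at 4 h and 4.98e-07 at 8 h for the flavonoid MYB subgroups. Leaving out each library gave 13186 to 14008, 15461 to 16167 and 14973 to 15782 genes at 2, 4 and 8 h, 10827 to 11811 for 4 against 2 h, 13648 to 14577 for 8 against 4 h, 19271 to 19585 at any time, an overlap of 8519 to 8894, 52 to 54 lists and 388 to 397 calls of named genes. Replicates sharing a number did not deviate together (residual correlations -0.036 to 0.028 over 18 pairs, and -0.043 to 0.051 for other pairs). With replicate number as a block the counts were 13893, 15999, 15606, 11666, 14397 and 19521, and no list call changed (52). At depths of 30468104 to 37395814 reads, 4687 genes had too few counts to pass the filter and were not tested.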

Other observations

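Pathway names deposited with the genes were tested only after the other results were seen. Genes of fatty acid degradation were mostly higher at 4 h (37 of 67 higher, 19 lower, camera adjusted p = 7.47e-06, 0.0558 with an estimated correlation), as were those of valine, leucine and isoleucine degradation (40 of 63 higher, 12 lower, 6.24e-07, 0.0887 with an estimated correlation) and autophagy (30 of 42 higher, 5 lower, 0.0323, 0.182 with an estimated correlation). Aminoacyl-tRNA synthesis genes were lower at 4 h (44 of 69 lower, 8 higher, 0.0244, 0.157 with an estimated correlation). Protein processing in the endoplasmic reticulum had 125 of 220 genes higher and 33 lower at 2 h (0.00380, 0.149 with an estimated correlation). At 8 h proteasome genes were higher (45 of 61, 2 lower, 0.0289, 0.340 with an estimated correlation) and genes of the folate one-carbon pool lower (16 of 18, 0 higher, 6.34e-04, 0.157 with an estimated correlation). Over 112 pathways and 3 times (336 tests), 39 passed with the preset correlation and 0 with an estimated one.

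Seed storage classes parted over time. Oleosin genes together went from 1.90 ± 0.230 to 45.0 ± 4.52 CPM at 8 h (n = 3) and vicilin genes from 30.1 ± 4.08 to 121 ± 5.74 CPM, while the 12S globulin gene stood at 10.2 ± 0.664 and 6.55 ± 0.907 CPM. The rise of the vicilin sum lay mostly in the gene evm.TU.Ft4.4147, so it does not speak for the class. These sums were not tested.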
